A study of Danio rerio with 8 samples.

How the data were processed

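The samples were 8 single-cell RNA libraries of fluorescent cells from zebrafish heads without eyes, 4 from controls wild type for stim2a and stim2b and 4 from double knockouts. Per the labels' protocols, about 8000 cells per sample were sorted for GCaMP5G fluorescence driven by the elavl3/HuC promoter and loaded on the 10x Chromium system with 3′ V3 chemistry. Per the file headers and the submitters' processing notes, the authors made the deposited UMI counts with Cell Ranger 6.1.2 on GRCz11 (danRer11), and the matrices hold barcodes called as cells. The release of the gene annotation and the depth of the raw reads are not given in the sources used here. The deposited values are whole-number UMI counts per gene and barcode, neither normalized nor pooled over replicates, for 26573 genes, of which 23559 had a count. Gene names came from the files, where 1146 gene IDs share a symbol with another and 779 have no symbol, and counts of near-identical paralogs are uncertain because reads may be split between them.

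Groups and replicate numbers were taken from sample titles. The groups, tests, gene lists, cell type markers, rule for named genes and most alternatives were fixed before the data were examined. Barcodes were kept with at least 500 UMIs, at least 300 detected genes and at most 10% of UMIs from mitochondrial genes. Of 14376 barcodes, 783 failed these limits. Doublets were scored per library with Scrublet in scanpy 1.11.5, and the highest scores were removed at 0.8% per 1000 barcodes, 206 cells or 1.52% of those that passed, which left 13387. The labels give no number of cells recovered. The files hold 1225 to 2576 barcodes per library, 15.3% to 32.2% of the cells sorted.

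For clustering, counts were scaled to 10000 per cell and log-transformed. The 2000 genes most variable within libraries, without stim2a and stim2b, gave 30 principal components, 15 neighbours and Leiden clusters at resolution 1, with no integration across libraries (Python 3.11.15, scikit-learn 1.9.0, python-igraph 0.11.9). A cluster was named "X-like" when at least 3 markers of a type were at least 1 higher in log2 than in other cells, and when markers of no other type were as many among its 10 leading genes. A cluster led by the neuronal genes neurod2 and esrrb and a cluster led by isl2a and p2rx3a stayed unnamed because their leading genes went against the name given by their markers. Classes with at least 20 kept cells in each of the 8 libraries were tested for genes (14 classes), and those with at least 50 cells in all were tested for shares (26).

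Counts were summed per library, over all kept cells or within a class, and cells were never used as replicates. Group differences were tested with edgeR 4.0.16 (R 4.3.3), with TMM scaling, its default filter on low counts, robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05 (two-sided). Log2 fold changes are knockout against control, and CPM values, counts per 1e6, use TMM-scaled library sizes, except for the stim genes, whose CPM use the unscaled sum of UMIs. Class shares were tested with edgeR on cells per class, with the kept cells of a library as its size. The difference between glutamatergic and GABAergic neuron-like cells was an interaction term with the library as a block. Of 30 gene lists, 26 had at least 5 measured members in all cells and were tested with camera in limma 3.58.1, with a preset correlation of 0.01, with an estimated correlation, and with fry. The other 4 lists (photoreceptor and pineal genes, lens crystallins, erythrocytes and pigment cells) had fewer members and have no test. The ribosomal list was taken by name prefix, so it also holds S6 kinase genes, of which the files name 11. Median differences of a list are medians over its members of the difference in log2 CPM. Values of single measures per library were compared with an exact two-sided permutation test of 4 against 4, with 70 label assignments and a smallest p of 0.0286.

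The named genes were stim2a, stim2b, stim1a and stim1b, then the called genes with a mean of at least 5 CPM whose groups did not overlap, the 12 highest and 12 lowest in all cells and the 4 highest and 4 lowest within a class. Where fewer than 5 passed in a direction in all cells, the 5 with the smallest p were given as values. In lists that passed or held a call, up to 3 members with the smallest p were taken, and for the interaction the 5 genes with the smallest p. Clone-based names were skipped unless 5 or fewer genes were called. Some genes that this rule takes are not reported here.

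The tests were also run on simulated counts with 200 changed genes, drawn from those with at least 5 CPM. Cluster 23, which held most calls within classes in the real counts, was among the classes simulated. The simulation is therefore not taken as a check made blind to the real counts. In all cells 54% of genes changed by 2-fold and 95% of those changed by 4-fold were recovered among 13152 genes, with 9 false calls of 158. In GABAergic neuron-like cells the shares were 55% and 93% (6901 genes), in cluster 23 they were 59% and 81% (2594 genes), and for the interaction they were 19% and 80% (5368 genes). The 1 list raised by 1.5-fold was found with 1 other call, and the 2 changed shares were found with 1 other call. Genes were drawn independently there, whereas the estimated correlation in the real lists reached 0.526 (ribosomal) and 0.668 (epidermis). The simulation therefore cannot tell how often camera's preset correlation gives false calls in the real lists.

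The groups share replicate numbers. Deviations of log2 CPM from the group means correlated between same-numbered control and knockout libraries at 0.299, 0.148, 0.338 and 0.132 for numbers 1 to 4. The labels do not explain this. The main fits hold no term for the numbers, which were used as a pairing only in the replicate block and in some splits of the libraries. The correlations between unlike numbers were 0.181 to 0.408 within libraries 1 and 2 and within libraries 3 and 4, and all were negative across these sets. Unlike numbers of 1 set thus correlated as highly as same numbers, so a pairing by number cannot be told apart from the sets. Deviations sum to 0 in each group, which favours negative values across the sets where those within them are positive. No 2 libraries of a group agreed within the sampling noise of independent UMIs (chi-square per degree of freedom 5.36 to 30.0). UMIs of 1 cell are not independent, so these values do not show a difference beyond the sampling of cells.

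The alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, the replicate block, leaving out each library, doublets kept, all deposited barcodes, a mitochondrial limit of 5%, neuron-like clusters only, thinning to the shallowest total, the mean over cells of CPM with limma, other clusterings, TMM on shares, and other set tests. A term for libraries 1 and 2 against 3 and 4, the removal of cluster 22, the removal of cells over 15000 UMIs and the 5% limit for shares were chosen after seeing the data. The RefSeq table used here belongs to another assembly, GRCz12tu, so it served only for the order of genes, and no coordinates are given.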

Results

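Single-cell transcriptomes were collected from the heads, without eyes, of zebrafish larvae 5 days after fertilisation. The larvae carried a GCaMP5G calcium sensor under the elavl3/HuC promoter, an early neuronal marker, and fluorescent cells were sorted before droplet encapsulation. The 8 libraries came from 4 control samples, wild type for stim2a and stim2b, and 4 double knockout samples. Stim2 proteins sense calcium in the endoplasmic reticulum (ER) and open plasma membrane channels when these stores empty, a route named store-operated calcium entry. The comparison asks how cells of neuronal origin differ when both zebrafish Stim2 genes are disrupted. The labels do not say whether libraries of 1 group came from separate animals or clutches, so p-values measure the spread between these libraries, which may be technical.

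The deposited files held 14376 barcodes and 48744320 unique molecular identifiers (UMIs), and a library totalled 3793246 to 10808637 UMIs. After filtering, 13387 cells were kept. Kept cells had a median of 2839 ± 1022 UMIs in control libraries and 3810 ± 584 in knockout libraries (SD, n = 4 each), a difference of 971 that did not pass the exact permutation test (p = 0.171, adjusted p = 0.429 over 10 measures). The libraries with replicate numbers 1 and 2 parted from those numbered 3 and 4, although the labels name no batch. In libraries 1 and 2 the knockout medians were 2314.5 UMIs above the control medians on average, and in libraries 3 and 4 they differed by -372.5. Each value for all 8 libraries is therefore set beside the differences within libraries 1 and 2 and within libraries 3 and 4 where it is a main result.

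**Figure D1:**
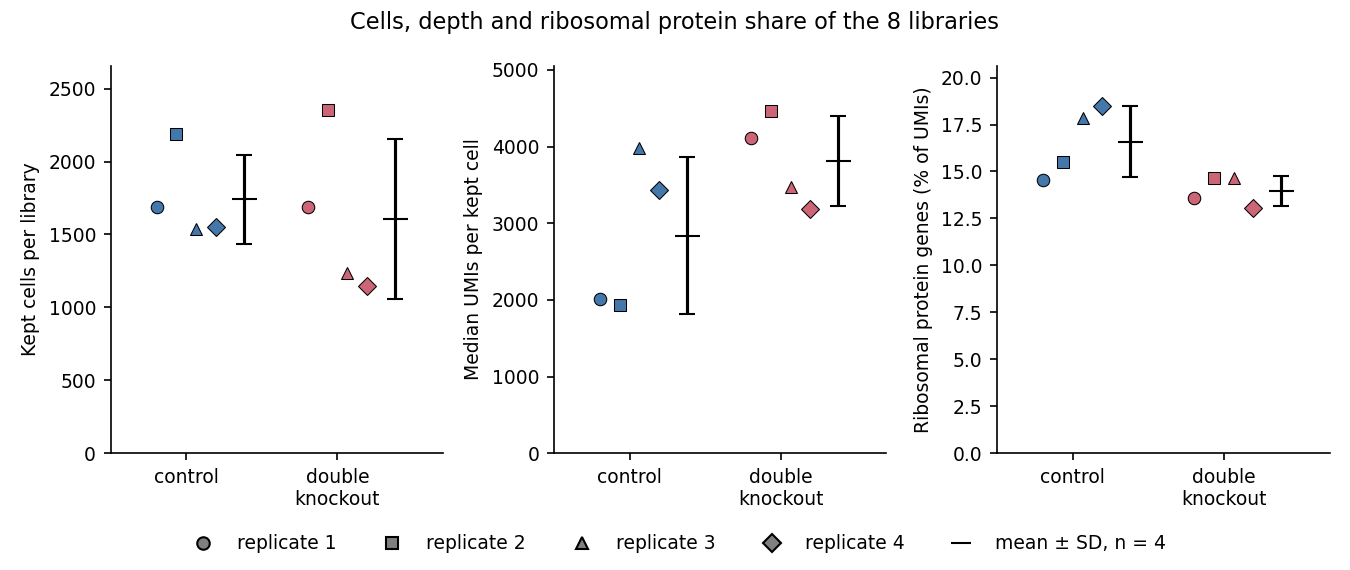
Kept cells, median UMIs per kept cell and the percentage of UMIs from ribosomal protein genes in each library, with control libraries in blue and double knockout libraries in red; bars give mean ± SD, n = 4. Controls 1 and 2 had median depths of 2018.5 and 1933 UMIs, below the 6 other libraries, and the ribosomal percentage was 16.6 ± 1.88 in controls and 13.98 ± 0.789 in knockouts.

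The targeted transcripts were near the detection limit in both groups. stim2a (ENSDARG00000074867) had 38 UMIs in all, with 0.828 ± 0.249 CPM in controls and 0.905 ± 0.466 in knockouts (SD, n = 4 each). Its fitted log2 fold change of -0.11 (SE 0.57) had the opposite sign to these means and did not pass edgeR's quasi-likelihood test (adjusted p = 0.942, without a low-count filter). stim2b (ENSDARG00000001776) had 98 UMIs, with 2.13 ± 0.429 CPM in controls and 2.03 ± 0.277 in knockouts (log2 fold change -0.18, SE 0.29, edgeR adjusted p = 0.782). No difference was detected in either, and at the depth of stim2a a 2-fold change lies within 2 standard errors of the estimate. The knockouts carry a deletion of 5 bp in exon 7 of stim2a and an insertion of 4 nt in exon 3 of stim2b. A 3′ tag outside such an edit checks little of the genotype. Of the paralogs, stim1a (ENSDARG00000060723) had 1885 UMIs and 38.2 ± 3.23 CPM in controls against 41.2 ± 2.54 in knockouts (log2 fold change 0.01, SE 0.10, edgeR adjusted p = 0.974), and stim1b (ENSDARG00000061560) had 15 UMIs.

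Clustering gave 32 clusters. Fixed markers named 18 of them in 14 classes, and 14 clusters stayed unnamed. Clusters with the markers shared by neurons held 12384 cells, 92.5% of those kept. GABAergic neuron-like cells (1763), tectal or midbrain neuron-like cells (1505), cluster 22 (1480) and glutamatergic neuron-like cells (996) held the most cells. Cluster 22 had a median of 762 UMIs, 0.217 of the median of its cells' own libraries, and stayed unnamed. Cluster 23 (482 cells) was led by the homeobox gene shox2, the zinc finger gene bnc2 and the glutamate transporter slc1a6. Its markers of thalamic neurons did not outnumber those of radial glia, so it too stayed unnamed. In the hindbrain or spinal interneuron-like cells the stress gene ddit3 was among the leading genes.

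In all kept cells, rnf34b, an E3 ubiquitin ligase gene, and bmf2, which encodes a pro-apoptotic relative of Bcl-2, rose in the knockouts, and mgst3b, a microsomal glutathione S-transferase gene, fell. rnf34b (ENSDARG00000054036) went from 8.40 ± 1.54 to 26.3 ± 4.08 CPM (log2 fold change 1.64, SE 0.18), bmf2 (ENSDARG00000041414) from 7.58 ± 0.476 to 20.7 ± 3.00 CPM (1.45, SE 0.16) and mgst3b (ENSDARG00000033364) from 133.5 ± 7.18 to 79.4 ± 4.34 CPM (-0.75, SE 0.09; SD, n = 4 in each group). Each had an adjusted p of 0.0333 in edgeR's quasi-likelihood test. Within libraries 1 and 2 the log2 differences of these genes were 1.58, 1.204 and -0.73, and within libraries 3 and 4 they were 1.65, 1.60 and -0.76. These 3 were the genes past the threshold among 13546 tested, while 2341 had an unadjusted p under 0.05. The 4 knockout values lay all above or all below the 4 control values in 12.19% of genes tested, where chance gives 2.86% on average over groupings. Genes vary together, so 1 grouping can lie far from this average without an effect of the genotype. Libraries 1 and 2 against 3 and 4, tested in the same way, gave 3099 genes with an unadjusted p under 0.05. With the replicate number as a block 0 genes passed in edgeR (adjusted p = 0.116 for each of the 3 genes), 2534 had an unadjusted p under 0.05, and DESeq2 on the same sums called 529. mgst3b did not pass when libraries were thinned (adjusted p = 0.0508), and neither it nor bmf2 passed with limma on the mean over cells of CPM (adjusted p = 0.0600). With 1 library left out, 21 genes passed without control 1 and 0 without any other of the 8 libraries, while the log2 fold changes stayed at 1.497 to 1.711 for rnf34b, 1.38 to 1.53 for bmf2 and -0.78 to -0.72 for mgst3b. With a term for libraries 1 and 2 against 3 and 4, added after the data were seen, 780 genes passed.

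The next genes by p-value did not pass. Of those higher in knockouts, these were doc2d, a calcium-binding double C2 domain gene (log2 fold change 0.93), fxyd6, a regulator of the sodium pump (0.71), shank3b, a postsynaptic scaffold gene (0.94), jpt1a (0.59) and the adducin gene add3b (1.62), which is also among the leading genes of cluster 23. Of those lower, they were the ribosomal protein genes rpl10a (-0.57) and rps26 (-0.51), the transcription factor subunit gene nfyba (-0.63), the peroxiredoxin gene prdx2 (-0.60) and the ER co-chaperone gene dnajb11 (-0.62). Their edgeR adjusted p-values ran from 0.0636 to 0.0722, and in each gene all 4 knockout libraries lay on 1 side of all 4 controls.

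Genes of the synapse were higher in the knockouts as groups. The 64 measured genes of the presynaptic vesicle machinery rose (median difference 0.24 in log2 CPM, 55 members higher, camera adjusted p = 4.32e-09), with an adjusted p = 0.0652 with an estimated correlation. None of its members passed over all genes and 15 rose when adjusted over the list alone, among them the synaptotagmin gene syt5b (log2 fold change 0.91, SE 0.18), napba (0.49, SE 0.10) and the vesicle protein gene syngr1a (0.45, SE 0.10). The 65 genes of the glutamate synapse rose too (median 0.38, camera adjusted p = 2.97e-08, adjusted p = 0.143 with an estimated correlation). Of these, 0 passed over all genes in edgeR and 19 rose when adjusted over the list alone, among them shank3b and the vesicular glutamate transporter gene slc17a7a (1.34, SE 0.29). The 42 genes of the GABA and glycine synapse had a median of 0.29 and rose (camera adjusted p = 0.000347, adjusted p = 0.328 with an estimated correlation), and a median of 0.18 without control 4. None passed over all genes and 5 rose when adjusted over the list alone, among them the receptor genes gabbr1b (0.57, SE 0.11) and gabrd (0.98, SE 0.22). In mean log2 CPM the knockouts exceeded controls by 0.26, 0.32 and 0.15 for these lists in libraries 1 and 2, and by 0.39, 0.46 and 0.44 in libraries 3 and 4. The ribosomal percentage of UMIs was lower in knockouts and the share of cluster 22 higher, and neither passed its test (exact permutation adjusted p = 0.381 and edgeR adjusted p = 0.0845). The difference in the cluster 22 share was 8.27 percentage points, and 1.08 when each library's UMIs were scaled to 1 median.

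Voltage-gated calcium channel genes and genes of calcium buffers, sensors and calmodulin signalling rose as well. The 29 channel genes had a median of 0.40 (26 higher, camera adjusted p = 1.11e-05, adjusted p = 0.0553 with an estimated correlation). None passed over all genes and 4 rose when adjusted over the list alone, including the subunit genes cacnb4a (0.63, SE 0.13), cacna2d2b (0.61, SE 0.15) and cacna1ha (0.63, SE 0.16). The 56 buffer and sensor genes had a median of 0.14 (camera adjusted p = 0.0110, adjusted p = 0.328 with an estimated correlation, 0.0583 without control 3 and 0.0987 without control 4), and in neuron-like clusters alone the median was 0.09 and the list did not pass (0.0920). None passed over all genes and 10 rose when adjusted over the list alone, among them the calmodulin-dependent kinase gene camk2b1 (0.48, SE 0.11), the calcineurin regulator rcan3 (0.46, SE 0.11) and the sensor ncs1a (0.61, SE 0.14). The 16 genes of ER calcium handling fell (median -0.17, camera adjusted p = 0.0147, adjusted p = 0.328 with an estimated correlation, 0.0583 without knockout 3 and 0.0827 without a low-count filter). None passed over all genes and 3 fell when adjusted over the list alone, namely the ER calcium-binding chaperone gene calr (-0.41, SE 0.09), the calcium pump gene atp2a2b (-0.52, SE 0.12) and pdia3 (-0.40, SE 0.11). Within libraries 1 and 2 and within libraries 3 and 4 the mean differences were 0.34 and 0.43 for the channels, 0.17 and 0.21 for the buffers and sensors, and -0.10 and -0.26 for ER calcium handling. The 10 genes of store-operated calcium entry did not pass (median 0.13, camera adjusted p = 0.100, fry adjusted p = 0.0363), with the channel gene trpc1 at 0.59 (SE 0.21). The 25 genes of plasma membrane and mitochondrial calcium transport did not pass either (median 0.17, camera adjusted p = 0.0832).

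Ribosomal protein genes were lower in the knockouts. The 93 measured members had a median of -0.29 (81 lower, camera adjusted p = 2.99e-18), with an adjusted p = 0.328 with an estimated correlation. Over all genes 0 passed in edgeR, and when adjusted over the list alone 39 fell and 2 rose. rpl10a went from 2796 ± 144 to 1880 ± 83.0 CPM, rps26 from 2165 ± 132 to 1523 ± 28.6 CPM and rpl39 from 5079 ± 443 to 3531 ± 213 CPM (SD, n = 4 each). The list mean differed by -0.06 in libraries 1 and 2 and by -0.38 in libraries 3 and 4. It did not pass an exact permutation test over libraries (p = 0.114, adjusted p = 0.297). Its value in log2 CPM was 9.51 in knockout 2 and 9.55 in knockout 3, above the 9.44 of control 1.

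Protein folding lists fell in the same cells. The 35 genes of the unfolded protein and integrated stress response had a median of -0.20 (camera adjusted p = 0.000771, adjusted p = 0.328 with an estimated correlation), and 6 of them fell when adjusted over the list alone against 0 over all genes, among them dnajb11 and the ER stress factor gene manf (-0.72, SE 0.15). The genes calr, pdia3 and hspa5 belong both to this fixed list and to that of ER calcium handling, so the falls of these lists are not separate results. The 25 heat shock and chaperone genes had a median of -0.18 (camera adjusted p = 0.000940, adjusted p = 0.369 with an estimated correlation). None passed over all genes, and 1, the mitochondrial chaperonin gene hspe1 (-0.68, SE 0.13), fell when adjusted over the list alone. The mean of this list differed by -0.45 in libraries 1 and 2 and by 0.04 in libraries 3 and 4, and that of the stress response list by -0.17 and -0.09. Neither mean passed the exact permutation test over libraries (p = 0.429 for heat shock and 0.257 for the stress response). The heat shock median ran from -0.33 without knockout 4 and -0.28 without knockout 3 to -0.12 without control 3, -0.10 without knockout 1 and -0.098 without knockout 2, and the stress response median from -0.35 without control 4 and -0.33 without control 3 to -0.12 without control 2. Nuclear genes of oxidative phosphorylation fell slightly (95 members, median -0.09, camera adjusted p = 0.000119, adjusted p = 0.514 with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone. Their mean differed by -0.09 in libraries 1 and 2 and by -0.04 in libraries 3 and 4, and their median was -0.05 without control 4 or knockout 1.

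Immediate early genes, which neurons induce on activity and which dissociation can also induce, rose as a list of 38 (median 0.34, camera adjusted p = 0.00480, adjusted p = 0.544 with an estimated correlation, and 0.119 without control 1). None passed over all genes, and egr1 (0.55, SE 0.12) and junbb (0.69, SE 0.16), the 2 members past the test adjusted over the list alone, rose there. The list mean differed by 0.40 in libraries 1 and 2 and by 0.05 in libraries 3 and 4, and did not pass the exact permutation test over libraries (p = 0.429). Of the cell cycle list, 45 of 51 genes were lower (median -0.47, camera adjusted p = 0.000124, adjusted p = 0.514 with an estimated correlation). In it 0 genes passed over all genes, and adjusted over the list alone the cyclin gene ccnf rose (1.34, SE 0.29) and hmgb2b, a chromatin protein gene, fell (-0.48, SE 0.11). The means differed by -0.42 in libraries 1 and 2 and by -0.42 in libraries 3 and 4, and did not pass the exact permutation test over libraries (p = 0.343). In neuron-like clusters alone the list did not pass (median -0.12, camera adjusted p = 0.187), and its median was -0.75 without control 1, -0.30 without control 3 and -0.26 without knockout 1. The 57 genes of neuronal progenitors and neurogenesis passed as lower (median -0.05, camera adjusted p = 0.0442, adjusted p = 0.442 with an estimated correlation), but the median was 0.04 without control 3 and 0.03 without control 4, and the adjusted p was 0.0570 without knockout 1, 0.171 without knockout 4, 0.0611 with RLE size factors, 0.0567 at a mitochondrial limit of 5% and 0.0629 without cluster 22. No member passed, and their mean differed by 0.23 in libraries 1 and 2 and by -0.34 in libraries 3 and 4.

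Epidermal and vascular marker lists were lower in the knockouts. All 24 measured epidermal genes had a lower fitted value (median -2.58, camera adjusted p = 1.20e-08, adjusted p = 0.328 with an estimated correlation). In neuron-like clusters alone the list did not pass (median -0.07, camera adjusted p = 0.171), and without cells over 15000 UMIs its median was -0.72. The annexin gene anxa1a, at 34.6 ± 17.2 CPM in controls and 8.37 ± 2.45 in knockouts, fell when adjusted over the list alone, and 0 members passed over all genes. The keratin gene krtt1c19e was at 103 ± 109 and 1.44 ± 1.89 CPM. The list mean was low in control 1 (1.34 in log2 CPM) and reached 6.62 in control 2, and it differed by -2.70 in libraries 1 and 2 and by -2.43 in libraries 3 and 4. The 21 vascular and mesenchymal genes fell as well (median -0.62, camera adjusted p = 0.00488, adjusted p = 0.514 with an estimated correlation), but not without control 2 (adjusted p = 0.102), control 4 (0.0854) or knockout 1 (0.0860). The median was -0.013 without cells over 15000 UMIs (adjusted p = 0.616) and 0.25 in neuron-like clusters alone (adjusted p = 0.351). None of them passed over all genes or over the list alone, and their mean differed by -1.05 in libraries 1 and 2 and by -0.18 in libraries 3 and 4.

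The remaining lists did not pass. Microglia and leukocytes (median -0.32, camera adjusted p = 0.0590), neuropeptides and hormones (0.30, 0.101) and the mitochondrial genome (-0.21, 0.0977) passed with the replicate block (camera adjusted p = 0.0462, 0.0366 and 0.0336), where each had an adjusted p = 0.352 with an estimated correlation. The circadian clock (0.13, camera adjusted p = 0.113), glia and myelin (-0.04, 0.105), monoaminergic and cholinergic genes (0.07, 0.559), hypoxia and glycolysis (0.06, 0.607) and apoptosis and p53 targets (-0.04, 0.831) did not pass. Skeletal muscle had a median of 0.03, a mean of -0.21 and a camera direction of lower (adjusted p = 0.559). Of the 26 lists tested 15 passed with camera's preset correlation, 6 higher and 9 lower, 0 passed with an estimated correlation, and 6 passed with fry, which tests whether the members move 1 way on balance. Of these 6, store-operated calcium entry and the circadian clock were not among the 15. In the exact permutation test of list means over libraries the lowest adjusted p was 0.106, reached among others by the presynaptic, glutamate synapse and calcium channel lists.

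**Figure D2:**
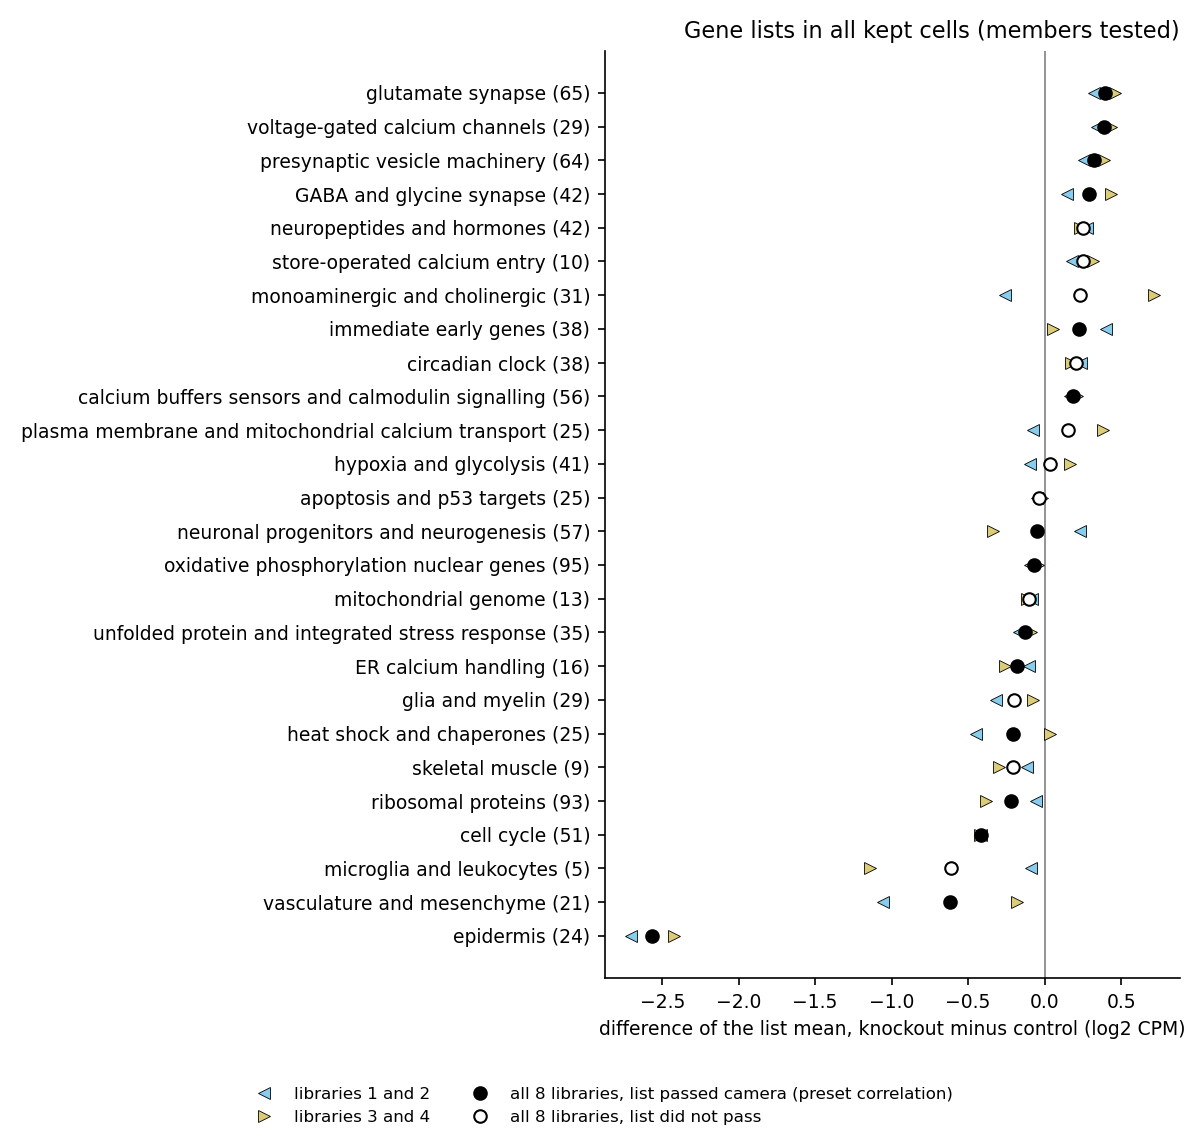
Difference of each list's mean log2 CPM between knockout and control libraries in all kept cells, with the number of members tested in brackets; filled circles mark lists past camera's preset test and triangles give the differences within libraries 1 and 2 and within libraries 3 and 4. The glutamate synapse list lay at 0.39 and the epidermis list at -2.56, and the progenitor list lay on opposite sides of 0 in the 2 sets of libraries.

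Cerebellar granule cell-like cells took a larger share of the knockout libraries. Their share rose from 1.01 ± 0.222% in controls to 2.35 ± 0.719% in knockouts (SD, n = 4 each), with all 4 knockout libraries above all 4 controls. The log2 change was 1.22 (SE 0.29, edgeR adjusted p = 0.0471 over 26 classes), and the exact permutation test gave p = 0.0286, the smallest that 70 label assignments allow, and an adjusted p = 0.248. The difference was 1.89 percentage points in libraries 1 and 2 and 0.788 in libraries 3 and 4. Purkinje cell-like cells, the other cerebellar class, were at 1.41 ± 0.416% and 1.18 ± 0.282% and did not differ past the test (log2 change -0.24, SE 0.28, adjusted p = 0.652). Cells were sorted for the sensor and had to hold 500 UMIs, and the knockout cells were deeper in libraries 1 and 2, so shares can also depend on the sort and on depth. The edgeR adjusted p was 0.0619 with the replicate block, 0.0557 with doublets kept, 0.0834 with components centred per library and 0.0502 at a mitochondrial limit of 5%. Leaving out 1 library gave 0.0971 without control 1, 0.0827 without control 2, 0.0540 without control 3, 0.0553 without control 4, 0.158 without knockout 1, 0.153 without knockout 2, 0.0154 without knockout 3 and 0.131 without knockout 4.

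The low-UMI cluster 22 held 7.23 ± 3.32% of control cells and 15.5 ± 1.64% of knockout cells, higher in all 4 knockout libraries, without passing the test (log2 change 1.103, SE 0.32, edgeR adjusted p = 0.0845). It passed with TMM on cells per class (adjusted p = 0.0382), with the term for libraries (0.0114) and without control 3 (0.0460). The difference was 10.4 percentage points in libraries 1 and 2 and 6.09 in libraries 3 and 4. Each library's UMIs were also scaled to 1 median and the minimum of UMIs applied again. The mean difference was then 1.08 percentage points against 8.27 before (exact permutation p = 0.2). Knockouts 3 and 4 (5.47 and 6.43%) stayed above controls 3 and 4 (3.03 and 3.14%). Knockouts 1 and 2 (4 and 3.57%) lay between controls 1 and 2 (3.46 and 5.53%). An effect of depth on this share therefore cannot be told apart from the genotype. The telencephalic neuron-like share was 3.85 ± 0.755% and 5.09 ± 0.843% (adjusted p = 0.425). The shares of cluster 14, led by the neuronal transcription factor gene neurod2 (3.21 ± 0.348% and 2.52 ± 0.161%, adjusted p = 0.425), and of cluster 8, led by sp5l and barhl1a (5.999 ± 0.665% and 4.54 ± 0.973%, adjusted p = 0.425), did not pass.

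**Figure D3:**
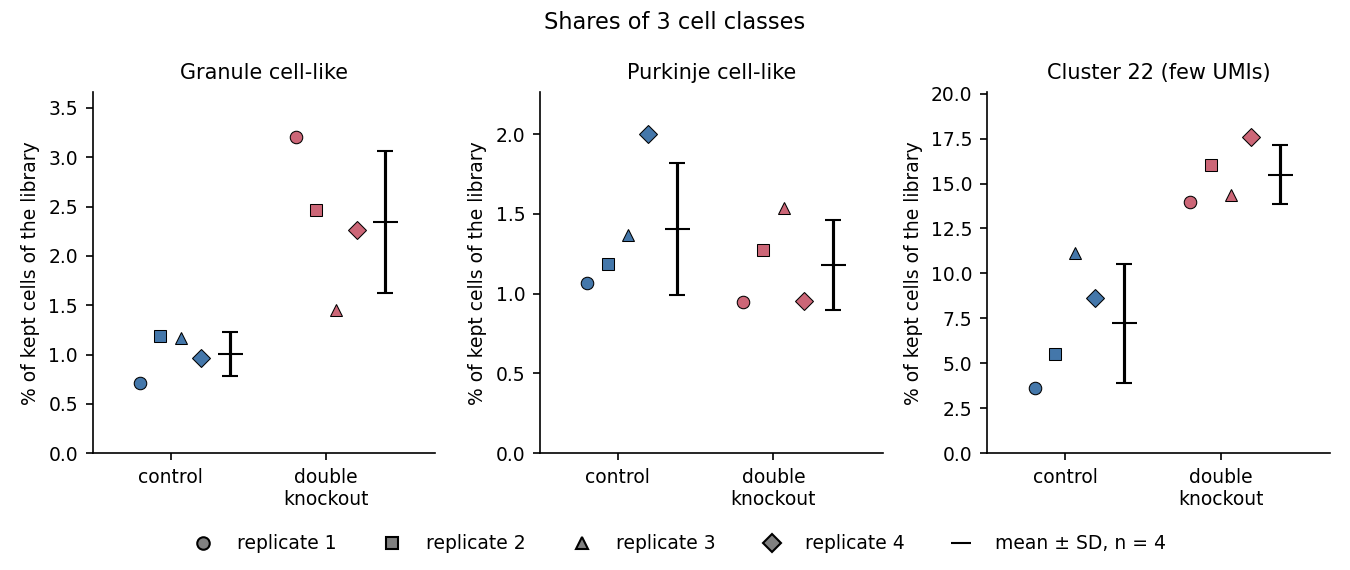
Shares of granule cell-like cells, Purkinje cell-like cells and cluster 22 among the kept cells of each library, in percent, with mean ± SD, n = 4. Granule cell-like shares were 0.712 to 1.19% in the controls and 1.45 to 3.20% in the knockouts.

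Within cell classes, most calls fell in cluster 23, and 4 other classes had 1 to 3. In hindbrain or spinal interneuron-like cells the metabotropic glutamate receptor gene grm2b (ENSDARG00000007195) rose from 82.2 ± 37.4 to 309 ± 106 CPM (log2 fold change 2.00, SE 0.35, edgeR adjusted p = 0.0323), and zgc:110425 rose by 2.23 (SE 0.42, adjusted p = 0.0484). In hypothalamic or neuropeptidergic neuron-like cells hnrnpa0a (ENSDARG00000089302), which encodes an RNA-binding protein, fell from 1333 ± 136 to 704 ± 71.1 CPM (-0.91, SE 0.15, adjusted p = 0.0270). In cluster 8 the immediate early gene fosab (ENSDARG00000031683) rose from 311 ± 71.5 to 721 ± 167 CPM (1.24, SE 0.20, adjusted p = 0.0254), with an adjusted p = 0.0778 under the replicate block. In cluster 22 the hypothalamic homeobox gene otpb (-2.21, SE 0.39, adjusted p = 0.0136), the Ras-related gene rasd4 (-1.56, SE 0.26, adjusted p = 0.0132) and the helix-loop-helix inhibitor gene id4 (-1.09, SE 0.22, adjusted p = 0.0482) fell. The other 9 of the 14 classes had 0 calls in edgeR, with 225 to 656 genes at an unadjusted p under 0.05. With doublets kept 0 genes passed in the hindbrain or spinal class, cluster 8 or cluster 22 (adjusted p = 0.218 for grm2b, 0.397 for fosab, 0.245 for otpb, 0.449 for rasd4 and 0.255 for id4). At a mitochondrial limit of 5% 0 passed in clusters 8 and 22 and 1 in the hindbrain or spinal class, and with components centred per library 0 passed in cluster 22 and grm2b did not pass (0.425). The replicate block gave 3 genes in the hindbrain or spinal class, 2 in the hypothalamic class, 0 in cluster 8, 5 in cluster 22, 1 in cluster 6 and 2 in cluster 11. Leaving out 1 library gave 0 to 3 calls in the hindbrain or spinal class (1 without control 1, 0 without control 2, control 3 or knockout 1, and 1 without knockout 4), and 0 to 2 in the hypothalamic class (0 without control 1, control 3 or any knockout, 2 without control 4). It gave 0 to 3 in cluster 8 (0 without control 1, 2 or 3 or knockout 1 or 2, 3 without knockout 3, 2 without knockout 4) and 0 to 12 in cluster 22 (0 without control 2 or knockout 2, 12 without control 3, 1 without knockout 1 or 3).

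In cluster 23 immediate early and synaptic genes rose and ribosomal protein genes fell, 83 genes up and 30 down of 2790 tested. fosab went from 155 ± 37.5 to 1175 ± 791 CPM (log2 fold change 2.89, SE 0.46), junba from 43.8 ± 28.1 to 300 ± 186 CPM (2.73, SE 0.48) and fosb from 74.6 ± 23.5 to 369 ± 143 CPM (2.28, SE 0.29), all transcription factor genes induced by activity. The vesicular glutamate transporter gene slc17a6a went from 57.9 ± 27.7 to 262 ± 95.5 CPM (2.21, SE 0.34). Of the genes that fell, hapln1a, an extracellular matrix link protein gene, changed by -1.23 (SE 0.29), sox4b, a transcription factor gene of immature neurons, by -1.07 (SE 0.21) and the cystathionine gamma-lyase gene cth by -1.05 (SE 0.29), with edgeR adjusted p-values of these 7 genes from 0.00171 to 0.0494. In the order named, the log2 differences of these genes were 2.79, 2.02, 2.45, 1.85, -1.17, -1.16 and -0.83 in libraries 1 and 2 and 2.52, 2.94, 1.82, 2.15, -1.48, -0.96 and -1.09 in libraries 3 and 4.

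By list, 9 of 20 immediate early genes rose in cluster 23, 14 when adjusted over the list alone (median 1.32). Of the presynaptic genes 7 of 32 rose, 22 when adjusted over the list alone (median 0.80), including stxbp1a (0.90, SE 0.19) and nrxn1a (1.38, SE 0.30). Of the glutamate synapse genes 5 of 18 rose, 13 when adjusted over the list alone (median 1.06), including the receptor genes grin2bb (1.32, SE 0.31) and gria3b (1.18, SE 0.29). Of the calcium buffer and sensor genes 6 of 29 rose, 9 when adjusted over the list alone (median 0.73), including camk2b1 (1.79, SE 0.37) and the calcineurin subunit gene ppp3r1a (1.14, SE 0.24). Of the ribosomal protein genes 10 of 79 fell, and when adjusted over the list alone 38 fell and 1 rose (median -0.41), including rpl39 (-0.64, SE 0.15). Camera's preset test passed for these 5 lists (adjusted p from 7.51e-18 to 1.65e-05 over all list and class pairs), and with an estimated correlation their adjusted p was at least 0.537.

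The number of calls in cluster 23 depended on single libraries, with 35 to 85 cells behind each sum. Without control 1 it was 69, without control 3 it was 34, without control 4 it was 1, without knockout 1 it was 4, without knockout 2 it was 17, without knockout 3 it was 365 and without knockout 4 it was 36. The 1 gene called without control 4 was fosb. The count was 57 with doublets kept, 263 without a low-count filter, 178 with the term for libraries and 203 with the replicate block. cth did not pass with the block (adjusted p = 0.0651), with doublets kept (0.0862), at a mitochondrial limit of 5% (0.0684) or without a filter (0.0811).

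**Figure D4:**
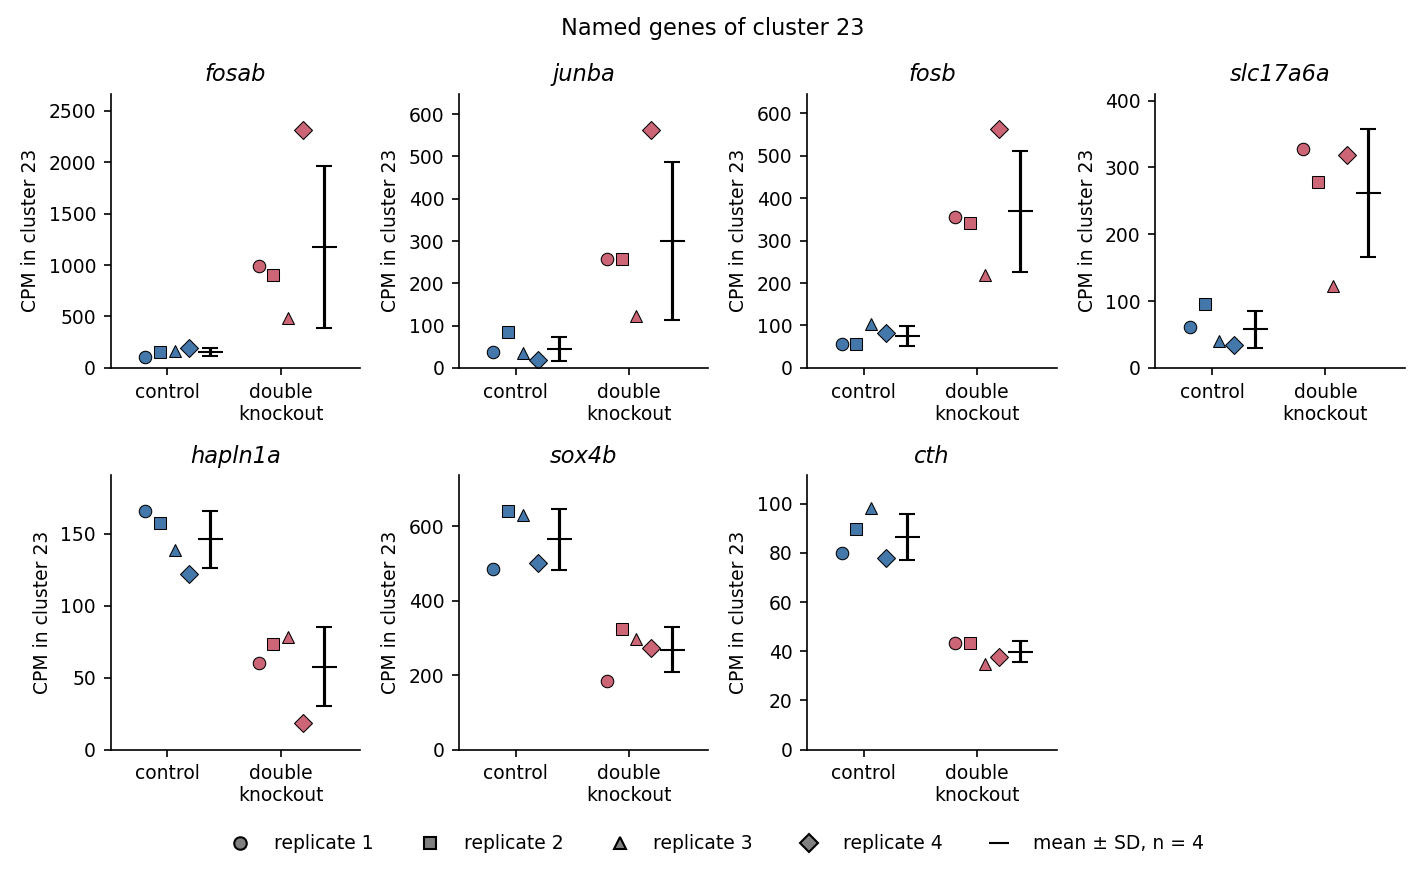
CPM of 7 named genes of cluster 23 in each library, with control libraries in blue and double knockout libraries in red, and mean ± SD, n = 4. For fosab the controls had a mean of 155 CPM and the knockouts 1175 CPM, with the widest spread among the knockouts.

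Across the 14 classes, ribosomal protein genes were lower in 11 classes by camera's preset test (medians from -0.41 to -0.08), and the mitochondrial genome was lower in 8 (-0.54 to -0.29). In all, 88 of 265 list and class pairs passed this test, 0 with an estimated correlation (lowest adjusted p = 0.487) and 0 with fry, and the following counts are by the preset test too. Immediate early genes were higher in 10 classes (0.28 to 1.32), presynaptic genes in 10 (0.13 to 0.93) and glutamate synapse genes in 7 (0.18 to 1.06). Heat shock and chaperone genes were lower in 5 classes (-0.48 to -0.15), ER calcium handling in 4 (-0.55 to -0.18) and the stress response list in 3 (-0.46 to -0.35). GABA and glycine synapse genes were higher in 5 classes and calcium buffers and sensors in 4. Voltage-gated calcium channel genes, higher in all cells, were higher in 0 of the 7 classes where they were tested and lower in 1, cluster 11 (-0.28). Nuclear genes of oxidative phosphorylation were lower in 4 classes and higher in 1, progenitor genes were lower in 3 and higher in 1, and the cell cycle list was lower in 1 of 8. In the glutamatergic neuron-like cells the ribosomal and presynaptic lists did not pass, while immediate early genes were higher and the mitochondrial genome lower. In cluster 18, a mix led by the keratin gene krt4 and by sparc, the presynaptic (0.93) and glutamate synapse lists were higher and the epidermis list was lower (-1.98). Without control 3, ribosomal genes were lower in 7 classes.

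**Figure D5:**
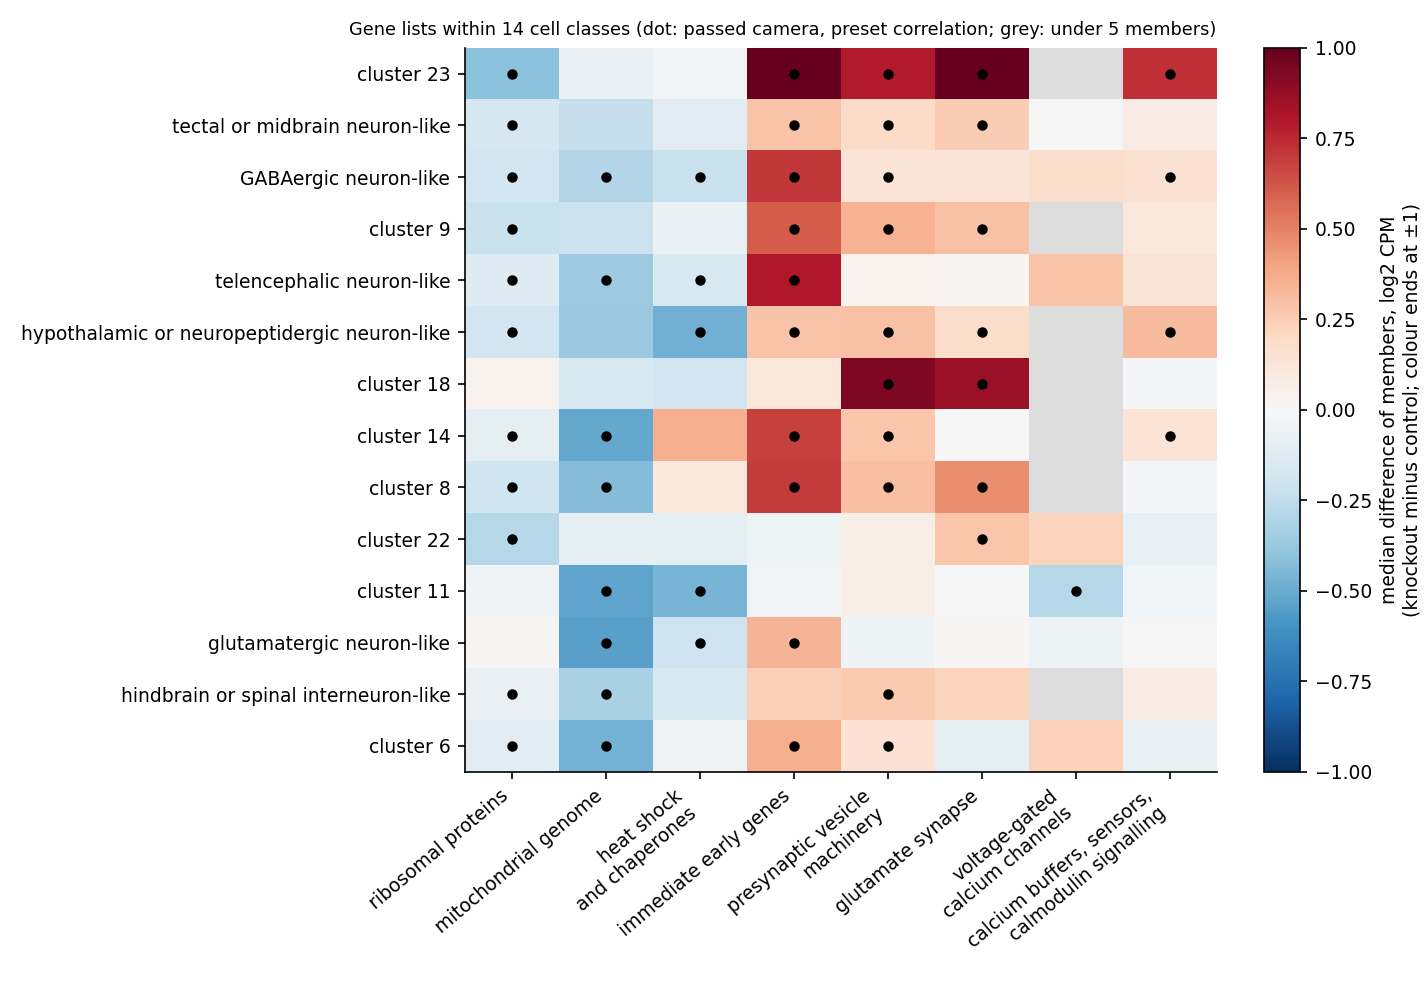
Median difference of the members of 8 gene lists in log2 CPM, knockout minus control, in the 14 tested classes, with a dot where camera's preset test passed over all list and class pairs and grey where under 5 members were tested. Ribosomal protein genes were lower in 11 classes and immediate early genes were higher in 10.

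The change in knockouts was compared between glutamatergic and GABAergic neuron-like cells, with the library as a block. The sodium pump gene atp1a1b (glutamatergic minus GABAergic difference 2.87, SE 0.50, edgeR adjusted p = 0.0104), the telencephalic homeobox gene emx1 (5.40, SE 0.93, adjusted p = 0.0456) and the transcription factor gene mafaa (4.85, SE 0.91, adjusted p = 0.0456) differed, 3 of 7797 genes tested, with 493 at an unadjusted p under 0.05. These differences rest on low counts, since mafaa reached the low-count filter of neither class fitted alone, emx1 not that of the GABAergic and atp1a1b not that of the glutamatergic class. atp1a1b did not pass with DESeq2 (adjusted p = 0.481), doublets kept (0.951), the 5% limit (0.926) or centred components (0.594). emx1 did not pass with DESeq2 (0.0712), RLE size factors (0.0513), doublets kept (0.504) or centred components (0.0662), and mafaa did not with DESeq2 (0.934) or RLE size factors (0.0513). The hypothalamic homeobox gene nkx2.4a (4.38, adjusted p = 0.0641) and the ribosomal stalk gene rplp1 (0.41, adjusted p = 0.270) came next and did not pass. emx1 is also a leading gene of a telencephalic cluster. The count was 1 without control 2, control 3 or knockout 3, and without knockout 4 nkx2.4a passed (adjusted p = 0.00359).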

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

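Of the tests in this part, the test of the granule cell-like share with scaled UMIs and the sub-cluster test of cluster 23 were set before their results were seen, and all the other tests of explanations, the splits included, were chosen after the results were seen.

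The share of granule cell-like cells was higher in all 4 knockout libraries, and this is weighed first. More cerebellar tissue in the knockout suspensions would raise Purkinje cell-like cells as well, but their share changed by -0.24 in log2, and with 2 standard errors added it reached 0.31, below the 0.61 that this explanation needs. A loss of shallow cells at the minimum of 500 UMIs is argued against as the whole cause, since with each library's UMIs scaled to 1 median and the minimum applied again the difference was 1.32 percentage points against 1.34 before (exact permutation p = 0.0286). Other effects of depth cannot be told apart from the genotype, because in libraries 3 and 4, where knockout cells were not deeper, the difference was 0.788 against 1.89 in libraries 1 and 2, with 2 libraries of each group. Chance cannot be excluded for the number of changed classes, because 2 of the 35 splits of the libraries gave at least 1 changed class. The other of these, with 4, was the split of libraries 1 and 2 against 3 and 4, which points to a structure of the libraries. Of the 8 splits that part all 4 numbered pairs the real one alone reached 1, with 0 in the highest other, but 8 are too few for a share under 0.05. A change of granule cells in the knockouts is a hypothesis that stays open, as may a difference in sorting, which was not tested.

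Ribosomal protein genes were lower and synaptic genes higher in the knockouts, the second pattern. More cells of the low-UMI cluster 22 do not account for it, since without that cluster the median fitted log2 fold change of the ribosomal list was -0.27 against -0.30 with it, and the presynaptic median was 0.23. Nor does a changed mix of classes, since the ribosomal median lay below 0 in 12 of the 14 classes. Deeper sequencing of knockout cells is argued against for the synaptic genes by libraries 3 and 4, where knockout cells were not deeper and the presynaptic mean was 0.39 higher, while the ribosomal mean differed by -0.38 there and by -0.06 in libraries 1 and 2. Chance cannot be excluded, since 7 of the 35 splits gave at least the 15 lists (highest other 16) and 4 gave at least the 88 list and class pairs (highest other 95), so a state of the cells that goes with the genotype may or may not lie behind it.

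Cluster 23 held 113 of the 120 calls within classes, the third pattern. Of the 35 splits of the libraries the real one alone gave as many calls, with 97 in the highest other. This cluster was followed because it held most calls under the real grouping, which favours that grouping, so the comparison does not exclude chance. The split of libraries 1 and 2 against 3 and 4 gave 233 calls within classes, 1 of them in cluster 23. Among the 8 splits that part all 4 numbered pairs the highest other gave 0, but 8 are too few for a share under 0.05. The larger of its sub-clusters held 53.1 to 68.9% of the cluster's cells in controls and 70.27 to 80.0% in knockouts. This other mix is argued against as the whole cause by the larger sub-cluster alone. There the median signed log2 change of these genes was 1.14 against 1.18 in the whole cluster, over the 103 tested in both. A fit of the larger sub-cluster alone called 36 genes, which were not matched to the calls of the whole cluster. The genes and their directions were picked in the whole cluster, which holds these same cells, so part of this likeness was set in advance. A stronger response to dissociation in knockout cells cannot be told apart from a change with the genotype. The 5 heat shock genes measured in cluster 23 had a median of 0.51 with a median standard error of 1.03. Activity of these cells before dissociation might also raise the same immediate early genes. Without control 4 the count was 1, without knockout 1 it was 4, without knockout 2 it was 17, without control 3 it was 34, without knockout 4 it was 36, without control 1 it was 69 and without knockout 3 it was 365.

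For the remaining counts, chance cannot be excluded either. In all cells 3 of the 35 splits gave at least 3 genes, and the split of libraries 1 and 2 against 3 and 4 gave 452, which points to a structure of the libraries other than the genotype. With a term for this structure the 780 genes compare with at most 263 in the other balanced splits, but 18 such splits are too few for a share under 0.05. Within classes 2 of the 35 splits gave at least 120 genes, and the split along that structure gave 233. For the difference between glutamatergic and GABAergic cells 6 splits gave at least 3 genes, with 8 in the highest other. Of the 8 splits that part all 4 numbered pairs, too few for a share under 0.05, the real one alone reached its count for the genes in all cells (highest other 1), the genes within classes (9), the list and class pairs (87) and the difference between glutamatergic and GABAergic cells (2), and 3 did so for the lists (16).

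A library stood apart from the 3 others of its group in 3 of 136 sets of 4 values, where chance gives about 5% of sets. The share of cluster 9 in knockout 3 was 2.83%, and the nearest knockout library was at 4.70% (gap 0.852 of the range). The share of oligodendrocyte or myelinating glia-like cells in control 4 was 1.36%, with the nearest at 0.868% (0.929 of the range). The level of prdx2 in control 4 was 465 CPM, with the nearest at 411 CPM (0.897 of the range).

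The change in knockouts differed between glutamatergic and GABAergic neuron-like cells for atp1a1b (2.87 in log2), emx1 (5.40) and mafaa (4.85), as tested by the interaction term. Without control 3 and without knockout 3 atp1a1b did not pass (edgeR adjusted p = 0.250 and 0.0641). emx1 passed without control 1 and without control 4 alone (0.00192 and 0.0373), and mafaa passed without control 1, control 4 or knockout 1 alone (0.00221, 0.0390 and 0.010).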

How the results depend on the processing

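The term for libraries 1 and 2 against 3 and 4, the removal of cluster 22, the removal of cells over 15000 UMIs and the 5% mitochondrial limit for shares were chosen only after the data were seen. Over 1777 comparisons of 91 single results with their alternatives, 1477 kept the direction and the side of the threshold, 187 were weaker, 97 were stronger and 16 were reversed. Where a value changed, the cause was not tested, unless stated. The few genes called in all cells had adjusted p-values just under the threshold and did not pass when any library but control 1 was left out: rnf34b ran from 7.40e-10 to 0.166, bmf2 from 3.04e-08 to 0.162 and mgst3b from 2.70e-13 to 0.182 over 21 alternatives, without a change of direction.

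The count of 3 genes in all cells was 529 with DESeq2 (218 up, 311 down), 7 with RLE size factors (2 up, 5 down), 1 with the mean over cells of CPM and limma, 8 at the 5% mitochondrial limit (2 up, 6 down), 11 in neuron-like clusters (2 up, 9 down), 5 without a low-count filter (2 up, 3 down), 10 without cells over 15000 UMIs (2 up, 8 down), 780 with the term for libraries (416 up, 364 down) and 0 to 21 when 1 library was left out. The 120 calls within classes were 200 with DESeq2 (134 up, 66 down), 62 with doublets kept (50 up, 12 down), 1087 without a low-count filter (664 up, 423 down, with more genes tested), 266 with the term for libraries (167 up, 99 down) and 7 to 380 when 1 library was left out. In that count control 1 gave 75, control 3 gave 48, control 4 gave 19, knockout 1 gave 7, knockout 2 gave 24, knockout 3 gave 380 and knockout 4 gave 47. The 3 genes that differed between classes were 1 with DESeq2, 1 with RLE size factors, 0 with components centred per library, 1 at the 5% limit (1 down), 22 without a filter (15 up, 7 down) and 1 to 4 when 1 library was left out. The 1 changed class share was 2 with TMM, 0 with centred components, 0 with doublets kept, 0 at the 5% limit, 3 with the term for libraries (2 up, 1 down) and 0 to 1 when 1 library was left out. The count of 15 lists was 0 with the estimated correlation, 6 with fry, 4 of them among the 15, and 14 to 18 when 1 library was left out. The 88 list and class pairs were 0 with the estimated correlation, 0 with fry and 74 to 102 when 1 library was left out. The median UMI difference was 669 to 1350 when 1 library was left out.

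With the replicate block, which pairs libraries of 1 number, 0 genes passed in all cells, 216 within classes (158 up, 58 down) and 0 class shares. It changed the call of bmf2, mgst3b and rnf34b (edgeR adjusted p = 0.116), cth in cluster 23 (0.0651), fosab in cluster 8 (0.0778) and the granule cell-like share (0.0619), and of no other of the 88 single results compared. Of the lists that did not pass in all cells, microglia and leukocytes, neuropeptides and hormones, and the mitochondrial genome passed with it, each with an adjusted p = 0.352 with an estimated correlation.

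stim2a was reversed at 0.12 when thinned to the shallowest total and at 0.073 without cluster 22, and ran from -0.41 to 0.20 when 1 library was left out. stim2b was at 0.10 with the mean over cells of CPM and ran from -0.28 to -0.13 when 1 library was left out, without a value for control 4 and knockout 1, where it did not reach the low-count filter. stim1a was at -0.016 with DESeq2, -0.023 with RLE size factors, -0.074 when thinned, -0.0017 at the 5% limit, -0.0014 in neuron-like clusters, -0.012 without a filter, -0.021 without cells over 15000 UMIs, -0.0025 without cluster 22 and -0.037 to 0.055 when 1 library was left out. Depth limits these values, with 38 UMIs of stim2a and 98 of stim2b in all. The recovery of 54% of genes changed by 2-fold in simulated counts does not apply to stim2a and stim2b. The changed genes there had at least 5 CPM, and both of these genes lie below that. The vascular list was at 0.25 in neuron-like clusters, and the progenitor list ran from -0.21 to 0.039 when 1 library was left out. The planned test of called genes in windows of 5, 10 and 20 Mb around stim2a and stim2b was not run because no annotation of the files' build was at hand, and the order of genes in another assembly took its place. All deposited barcodes gave values only for results over all cells.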

Other observations

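The tests in this part were chosen after the results were seen, except the planned edgeR fit, DESeq2 and the tests of the fixed lists.

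With a term for libraries 1 and 2 against 3 and 4, 780 genes passed edgeR's test in all cells, 416 higher and 364 lower in the knockouts, and 772 of them differed in the same direction within both sets of libraries. DESeq2 without the term also called 415 of them, all in the same direction. Neither count is independent support. The fit favours genes that differ alike in both sets of libraries, and DESeq2 was run on the same sums. Among the named genes that rose by the rule used for the report were the neuronal glutamate transporter slc1a6 (log2 fold change 1.49, SE 0.20), a leading gene of cluster 23, the vesicular transporter slc17a7a (1.297, SE 0.29), the postsynaptic scaffold gene shank2b (1.27, SE 0.27), the calcium-activated chloride channel gene ano1 (1.25, SE 0.21) and the kinase-like gene camkva (1.21, SE 0.20). Of the fixed lists, 17 of 64 presynaptic genes, 14 of 65 glutamate synapse genes, 6 of 42 GABA and glycine synapse genes and 4 of 29 voltage-gated calcium channel genes rose there and 0 fell, while 30 of 93 ribosomal protein genes fell and 1 rose. The genes that fell included the sterol synthesis gene dhcr7 (-0.95, SE 0.22), the ER glycoprotein sensor uggt1 (-0.95, SE 0.15) and the aminotransferase gene gpt2l (-1.31, SE 0.19). The 18 balanced splits are too few for a share under 0.05, with 263 genes in the highest other split.

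Single transcripts of other cell types, picked after their values were seen, were followed too. The lipid carrier apoeb, a microglial marker, was at 107 ± 15.7 CPM in controls and 49.4 ± 17.2 in knockouts (SD, n = 4 each) and did not pass in the planned fit (-1.12, SE 0.24, edgeR adjusted p = 0.101), but fell with the term for libraries (-1.16, SE 0.17, adjusted p = 0.0172). apoc1, a lipid carrier of microglia and liver, was at 198 ± 230 CPM in controls and 36.2 ± 46.4 in knockouts, so its spread covers the difference, and it differed by 2.07 in libraries 1 and 2 and by -2.72 in libraries 3 and 4. The endothelial junction gene cldn5b was at 5.24 ± 1.85 and 1.96 ± 0.542 CPM (edgeR adjusted p = 0.120, and 0.0191 with the term for libraries). A cluster of 21 cells held the liver genes apoa1b and fabp10a. The circadian clock list passed with fry (adjusted p = 0.00898) but not with camera, and bhlhe40, a clock repressor gene, had a log2 fold change of 0.51 (SE 0.12) and clocka one of 0.88 (SE 0.22), the 2 members that rose when adjusted over the list alone.

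In place of windows around the edited loci, the 25 tested genes on either side of stim2a and of stim2b were taken in the gene order of the GRCz12tu assembly, matched for 11630 of 13546 genes, 85.9%. Of the 50 neighbours of stim2b, 10 had an unadjusted p under 0.05 in edgeR, or 20% (exact 95% interval 10.0 to 33.7%), against 17.3% of genes elsewhere (Fisher's exact p = 0.575). For stim2a it was 5 of 50, or 10%, against 17.3% (Fisher's exact p = 0.258). In both sets 0 neighbours passed when adjusted over all genes.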
